A study of Mus musculus with 4 samples.

How the data were processed

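Transcript levels were measured on Affymetrix mouse 3′ expression arrays in LSK cells, the bone marrow fraction that lacks lineage markers and carries c-Kit and Sca1, which holds the haematopoietic stem cells and multipotent progenitors. Per the labels' protocols, marrow was flushed from the femurs of mice called wild-type, of a mixed background. LSK cells were sorted by the level of a c-Myc-eGFP fusion protein into a Hi and a Lo group, each with 2 arrays. Since the cells made this fusion protein, wild-type cannot mean that the mice lacked its gene. Total RNA was amplified from a few nanograms with a NuGEN Ovation kit and labelled with biotin, per the labels' protocols. Such amplification can compress or spread differences between transcripts.

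The deposited values are 1 intensity per probe set and array on a linear scale, and RMA is named in the submitters' processing notes. Its version, the software and the kind of background correction were not given in the sources used here. The lowest intensity on the arrays lay between 2.957 and 3.15 and the highest between 21288 and 22121.7, which is the range of linear values and not of log2 values, so the deposited intensities were log2-transformed here with no offset. RMA equalizes the distributions of the arrays, so a change in total RNA per cell would not appear in these values. The quartiles of the 4 arrays were close, with medians of 5.70, 5.71, 5.78 and 5.82 on the log2 scale.

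Of 45101 probe sets, 64 were controls and were left out of the tests, and 45037 remained. The platform annotation gave 1 gene symbol to 34945 of them, several to 932 and none to 9160; probe sets with several symbols were tested and not named. Symbols were updated through Entrez identifiers and a reference gene table of assembly GRCm38.p6, which matched 34741 probe sets and changed 59 symbols, and 204 kept their own symbol. A gene was represented by the probe set with the highest mean over the 4 arrays among those with that symbol alone, which gave 18161 genes, 9020 of them with over 1 probe set.

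The difference of Hi minus Lo was fitted over all 4 arrays with limma version 3.58.1 in R version 4.3.3 (lmFit, eBayes with a constant prior variance, no block, two-sided) and adjusted by the Benjamini-Hochberg method over the 45037 probe sets, with calls at an adjusted p under 0.05. The fit had 2 residual degrees of freedom and gained 1.976 from the prior. With 32 gene lists (817 genes, 743 of them measured), camera with a preset inter-gene correlation of 0.01 set the genes of a list against all other genes, adjusted over the 32 lists; camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way and compares them with no other gene, were alternatives. With an estimated correlation camera draws on the 2 residual degrees of freedom of the fit, and with the preset one on the number of genes. Small p-values are therefore much harder to reach with an estimated correlation. For each list the number of members past 0.05 is also given adjusted over the list alone. The tests, the lists, the alternatives and the rule for named genes were chosen before the data were examined, except where stated.

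The rule named Myc and Fbxw7, then per direction 12 genes with the largest difference among those past an adjusted p of 0.05 with both Hi arrays on the same side of both Lo arrays, leaving out unnamed gene models. Where fewer passed, the places went to the smallest unadjusted p under the same condition, given as values that did not pass. For each list with no member past 0.05 over all probe sets, the 2 members with the smallest unadjusted p were named. All other genes in the text were chosen after their values were seen. Of the 81 genes the rule named, 45 had over 1 probe set and 10 had a further probe set of opposite sign; Kdm5d alone had 1 of opposite sign at an unadjusted p under 0.05.

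For a gene that was dim in a group, a lower bound of the fold was formed. On each array the brightest of 27 control probe sets for bacterial transcripts that showed no added transcript marked the dim limit, between 4.735 and 4.872 on the log2 scale, a choice made after the data were seen. A gene at or under it on both arrays of a group has only a bound there, written as at least N-fold, from the mean of the bright group against the dim group's mean with its arrays set at that limit. All other folds are fitted differences on the log2 scale turned into ratios, and the error beside a difference is the moderated standard error of the fit.

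The steps were tested on simulated data with the means of the 45037 probe sets, variances drawn from the fitted prior and 200 probe sets changed. At 2-fold, 0 of 50 changed probe sets were called, at 4-fold 4 of 50, at 16-fold 40 of 50 and at 64-fold 42 of 50, with 6 unchanged probe sets called in all; the median estimates on the log2 scale were 1.04, 2.00, 3.97 and 6.01. A list shifted in the simulation was called and 0 other lists were. The probe sets were drawn independently of each other, so this does not test list calls among correlated genes. Few probe sets were changed, and variances were drawn without regard to intensity. In the data 8090 probe sets had an unadjusted limma p under 0.05. The share called after adjustment depends on how many differ, so the simulated shares are not the power of the real fit. The small number of arrays limits the precision. The labels do not say whether the 2 arrays of a group came from separate animals. The p-values of limma and fry thus measure only the spread between these samples, which may be technical. Those of camera with the preset correlation set a list against the spread between genes at that assumed correlation. They do not measure how far new samples would differ.

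The alternatives were a replicate block, leaving out each array, an intensity trend with robust hyperparameters, a filter on dim probe sets, quantile, median and cyclic loess scaling, leaving out probe sets that can match several transcripts, array weights, adjustment over 1 probe set per gene, a 2-fold limit, an ordinary test without moderation, the mean of all probe sets of a gene, and for lists an estimated correlation and fry. A fit over 1 probe set per gene and a filter on dim probe sets with an intensity trend were added after the data were seen. List genes without a probe set of their own, such as Ly6a (Sca1), were not analysed here, except that 4 probe sets shared by the adult globin genes were looked at after the data were seen.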

Results

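Genome-wide transcript levels were compared between LSK cells with a high and LSK cells with a low level of the c-Myc-eGFP fusion protein, each on 2 arrays. The title of the study concerns a ubiquitin ligase and its substrate in stem cell differentiation; Fbxw7 is the ligase subunit known to mark c-Myc protein for degradation. The comparison asks which transcripts go with the amount of c-Myc protein among LSK cells. These are a mixture of stem cells and multipotent progenitors, and their shares in Hi and Lo were not measured. Over all probe sets the log2 intensities of the 2 Hi arrays correlated at r = 0.99 and those of the 2 Lo arrays at r = 0.98, and the Hi and Lo arrays at r = 0.972 to 0.976. These correlations are across probe sets, which are not independent replicates.

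By camera with a preset correlation, 10 of the 32 gene lists were called higher and 8 lower in LSK cells with high c-Myc-eGFP, and with an estimated correlation 0 were called (smallest adjusted p = 0.157). Called higher were, among others, genes of DNA replication, mitosis, nucleotide synthesis, ribosome biogenesis and the erythroid and granulocyte-monocyte lineages. Called lower were, among others, genes of long-term haematopoietic stem cells, immediate early genes and MHC class II genes. By fry the erythroid and granulocyte-monocyte lists (adjusted p = 0.0533 each) and the MHC class II list (adjusted p = 0.0688) were not called. A sign of RNA quality also moved with the groups: the 3′ minus 5′ log2 intensity of the Gapdh controls was 0.63 and 0.66 in Hi and 0.74 and 0.78 in Lo, while that of Actb was 0.60 and 0.55 in Hi and 0.84 and 0.56 in Lo. Single probe sets did not pass: limma called 0 of 45037 higher and 0 lower at an adjusted p of 0.05 (smallest adjusted p = 0.0839), while 4075 were higher and 4015 lower at an unadjusted p under 0.05, against 2252 in all expected with no difference. The ordinary test without moderation called 0 higher and 1 lower. The mean of all probe sets of a gene, an alternative chosen beforehand, called 252 genes higher and 276 lower of 18161. A fit over 1 probe set per gene, added after the data were seen, called 190 higher and 215 lower. Both Hi arrays lay above both Lo arrays in 13203 probe sets and below both in 9915, together 51.3% where chance gives 33.3%.

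The Myc transcript itself (chromosome 15, 61985341 to 61990361 in GRCm38.p6) had a log2 intensity of 12.41 ± 0.003 in Hi and 11.17 ± 0.75 in Lo (SD, n = 2 each). The difference was 1.24 ± 0.40 (SE), 2.37-fold, with a limma adjusted p of 0.241, and it was 0.71 without Lo replicate 2 and 1.77 without Lo replicate 1. Pvt1, a long non-coding RNA gene that neighbours Myc, had 8.39 ± 0.82 in Hi and 4.46 ± 0.37 in Lo (SD, n = 2 each), at least 12.4-fold higher in Hi with an adjusted p of 0.0947. Pvt1 was chosen after its values were seen, and its other probe sets differed by 0.15 to 3.83. Fbxw7 (chromosome 3, 84814990 to 84979198) had 10.91 ± 0.26 in Hi and 10.52 ± 0.66 in Lo (SD, n = 2 each). Its difference of 0.39 ± 0.38 (SE) was no larger than the spread between replicates. Leaving out single arrays, it ran from -0.08 without Lo replicate 2 to 0.85 without Lo replicate 1, and it was 0.22 with the mean of its probe sets.

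The 12 genes with the smallest p in each direction all had the same adjusted p of 0.0839 and did not pass. With the mean of all probe sets of a gene, 48 of the 81 named genes passed 0.05. That alternative was a new fit over 18161 genes, which called 252 higher and 276 lower. Slc38a5 and Sult1a1 passed in it with unchanged log2 differences of 4.78 and -4.27, so averaging alone did not give these calls. On the higher side the amino acid transporter gene Slc38a5 was at least 19.0-fold higher in Hi, the protease gene Prss50 at least 6.87-fold, the sulfate transporter gene Slc26a1 at least 5.39-fold, Tlcd4 at least 7.27-fold and Cachd1 at least 5.52-fold. Bcat1, an enzyme of branched-chain amino acid metabolism, was 9.26-fold higher and the Rh-associated glycoprotein gene Rhag of the red cell membrane 8.60-fold. The exonuclease gene Exo1 was 5.48-fold higher, Igll1, a part of the surrogate light chain of B cell precursors, 4.75-fold, the cell cycle transcription factor genes Mybl2 and E2f1 4.38-fold and 3.83-fold, and the recombination gene Rad51ap1 3.63-fold. On the lower side the corepressor gene Runx1t1 was at least 9.85-fold lower in Hi, the efflux pump gene Abcb1a at least 11.9-fold, Creb5 at least 5.57-fold, Plekhb1 at least 3.76-fold and Adgrg2 at least 2.57-fold. The sulfotransferase gene Sult1a1 was 19.3-fold lower, Cd7 8.17-fold, Dlg2 6.80-fold, Ddx25 6.14-fold and the T cell receptor gamma segment Trgv4 5.74-fold. The pantetheinase gene Vnn1 was 5.50-fold lower and the transglutaminase gene Tgm2 4.90-fold. Some of these values depend on the probe set: with the mean of all probe sets of a gene the log2 difference was 1.41 for Bcat1, against 3.21, 1.34 for Igll1, against 2.25, and -1.02 for Dlg2, against -2.76. It was -1.31 for Runx1t1, -1.38 for Adgrg2 and -1.04 for Creb5, against fitted values of -4.59, -2.77 and -2.55.

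**Figure D1:**
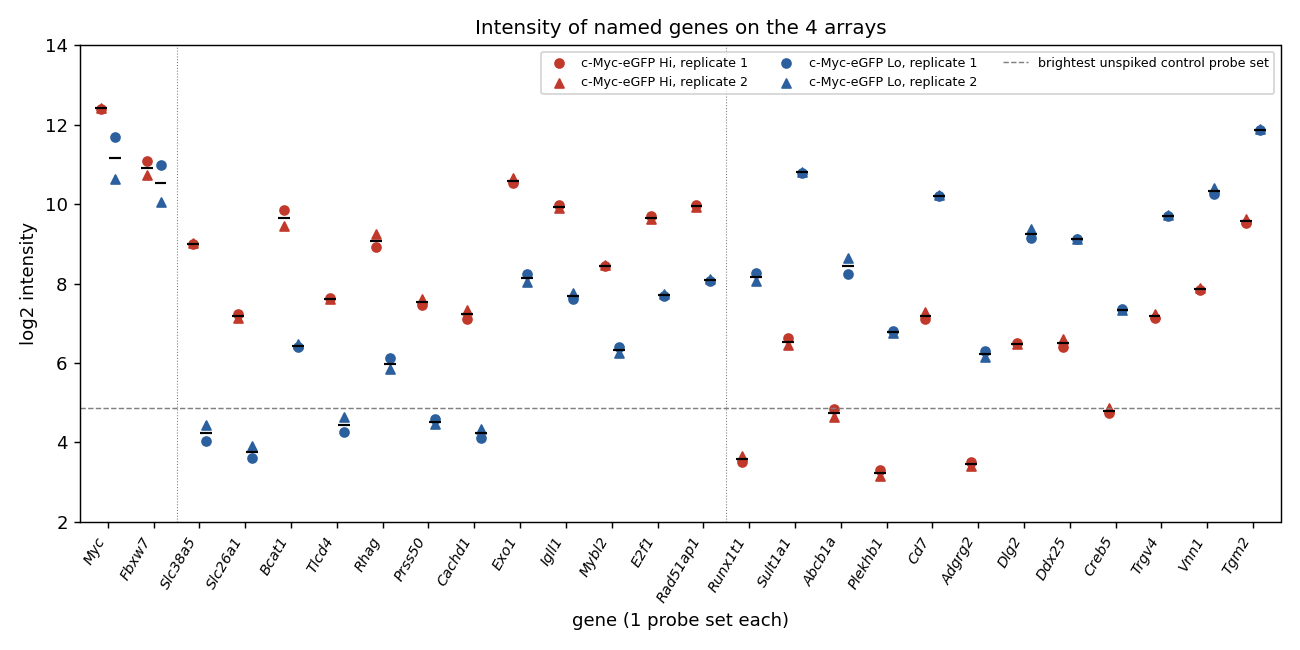
Log2 intensity (vertical axis) of Myc, Fbxw7 and the 12 genes of each direction with the smallest p (horizontal axis, 1 probe set each) on the 4 arrays; red marks are the c-Myc-eGFP Hi arrays, blue marks the Lo arrays, circles replicate 1, triangles replicate 2, short bars the mean of 2 arrays, and the dashed line the brightest unspiked control probe set. The 24 genes were selected for Hi and Lo marks that do not overlap, and the marks of Fbxw7 overlap.

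Genes of DNA replication rose in Hi as a list (median log2 difference 1.01, adjusted p = 2.44e-20 by camera; adjusted p = 0.252 with an estimated correlation). All 38 measured members were higher, 36 of them past 0.05 adjusted over the list alone, and for this and each other list 0 members passed over all probe sets. The replication origin factor gene Mcm10 differed by 2.41 ± 0.19 (SE) on the log2 scale and Ung, which removes uracil from DNA, by 1.85 ± 0.16, and the licensing factor genes Cdc6 and Cdt1 by 1.56 ± 0.16 and 1.25 ± 0.13. The members that did not pass were Mcm3 at 0.37 ± 0.27 and Chaf1b at 0.25 ± 0.27. Genes of mitosis and G2/M rose (median 0.89, adjusted p = 6.31e-18; adjusted p = 0.157 with an estimated correlation). Of 41 measured members, 31 were higher and 0 lower adjusted over the list alone. Mybl2 differed by 2.13 ± 0.14 (SE) and the mitotic kinase gene Cdk1 was 2.82-fold higher, while the proliferation marker Mki67 stood at 0.20 ± 0.30 and the cyclin gene Ccnb2 at -0.05 ± 0.13. Genes of G1 cyclins, CDKs and E2Fs rose (median 0.69, adjusted p = 2.13e-06; adjusted p = 0.252 with an estimated correlation). Of 17 measured members, 7 were higher and 0 lower adjusted over the list alone. These 7 were E2f1, E2f2, E2f7, E2f8, Ccne1, Ccne2 and Skp2, with differences from 0.83 for E2f2 to 2.31 for Ccne1. The D-type cyclin genes Ccnd1 and Ccnd2, which act earlier in G1, had differences of -0.03 ± 0.22 and -0.20 ± 0.14.

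Genes of nucleotide, one-carbon and polyamine synthesis rose in Hi (median 0.72, adjusted p = 1.98e-10; adjusted p = 0.299 with an estimated correlation). All 25 were higher, 12 past 0.05 adjusted over the list alone, among them Mthfd2 of the mitochondrial folate pathway, 3.03-fold higher, and the CTP synthase gene Ctps at 1.33 ± 0.16 (SE). Ribosome biogenesis genes rose (median 0.53, adjusted p = 3.47e-10; adjusted p = 0.299 with an estimated correlation). Of 44 measured members, 9 were higher and 0 lower adjusted over the list alone, led by Bysl at 1.56 ± 0.15 and Utp18 at 1.14 ± 0.13, both needed for small subunit assembly. With the mean of all probe sets of a gene these were 1.02 and 0.60. The canonical Myc targets rose (median 0.44, adjusted p = 9.82e-09; adjusted p = 0.299 with an estimated correlation). Of 38 measured members, 13 were higher and 0 lower adjusted over the list alone, and 13 of its 38 members stand on another list too. Tmem97 differed by 1.44 ± 0.13, the transferrin receptor gene Tfrc by 2.10 ± 0.26 and the spermidine synthase gene Srm by 1.15 ± 0.17; the nucleolin gene Ncl stood at 0.19 ± 0.14 and Ldha at 0.14 ± 0.14.

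Oxidative phosphorylation genes rose by less (median 0.23, adjusted p = 2.27e-04; adjusted p = 0.497 with an estimated correlation), and 0 of 38 passed adjusted over the list alone. The cytochrome c gene Cycs had a difference of 1.02 ± 0.13 (SE) and the complex subunit gene Ndufa4 of 0.56 ± 0.14. Translation initiation and tRNA synthetase genes rose (median 0.24, adjusted p = 0.00592 by camera and 0.476 with an estimated correlation), again with 0 of 29 past 0.05 adjusted over the list alone. The initiation factor gene Eif2b3 had a difference of 1.01 ± 0.22. Eif4ebp1, whose protein binds the initiation factor eIF4E and represses initiation, had 0.62 ± 0.15. With the mean of all probe sets of a gene Cycs had 0.57 and Eif4ebp1 0.16. The median of this list was 0.13 without Lo replicate 1. The ribosomal protein genes themselves were not called (27 measured, median -0.02, adjusted p = 0.837, 0 past 0.05 adjusted over the list alone), and their median was 0.07 after the arrays were shifted to 1 median. Rpl14 stood at 0.30 ± 0.18 and Rps6 at -0.24 ± 0.20, or -0.55 with the mean of all probe sets. The Myc network, that is Myc, its partners and its antagonists, was not called (19 measured, median -0.15, or 0.04 with the mean of all probe sets of a gene, adjusted p = 0.349), with 1 member higher adjusted over the list alone, the ubiquitin ligase subunit gene Skp2 at 1.49 ± 0.19. The paralogue Mycn stood at -0.90 ± 0.19, or -0.39 with that mean.

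Long-term haematopoietic stem cell genes fell in Hi (median -1.09), with the smallest p of all lists by camera with the preset correlation (adjusted p = 4.65e-21). With an estimated correlation the adjusted p was 0.157, the same as for the mitosis list. By fry it was 0.0164, against 0.00521 for the mitosis list. Of 59 measured members 38 were lower and 0 higher adjusted over the list alone. Sult1a1 had a difference of -4.27 ± 0.14 (SE), and Abcb1a was at least 11.9-fold lower. The endothelial protein C receptor gene Procr stood at -2.00 ± 0.17, the angiopoietin receptor gene Tek at -1.73 ± 0.14 and the transcription factor genes Hlf and Mecom at -1.15 ± 0.14 and -0.96 ± 0.18. Adhesion and niche genes fell (median -0.22, adjusted p = 0.0107; adjusted p = 0.299 with an estimated correlation). Of 36 measured members, 6 were lower and 1 higher adjusted over the list alone. The 6 lower members were Tek, Jup, Icam1, Robo4 and the junction genes Esam and Jam3, with Esam at -2.01 ± 0.24 (SE). Of the list, 8 of the 36 members stand on another list too, among them Tek, Robo4, Esam and Jam3 on the long-term stem cell list. Most of the lower members are thus stem cell genes already counted there. The median of the adhesion list was -0.14 without Lo replicate 2. The higher member was Vcam1 at 1.96 ± 0.40.

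Cell cycle inhibitor and quiescence genes fell (median -0.37, adjusted p = 0.0363; adjusted p = 0.319 with an estimated correlation). Of 27 measured members, 6 were lower and 3 higher adjusted over the list alone. Of the 27, 10 stand on another list too, among them Egr1, Nr4a1, Btg2 and Zfp36 on the immediate early and dissociation stress list. The cyclin-dependent kinase inhibitor gene Cdkn1c had a difference of -1.94 ± 0.25 (SE), Egr1 of -1.65 ± 0.14 and Foxo1 of -1.14 ± 0.17. The 3 higher members were the retinoblastoma family genes Rb1 at 0.71 ± 0.14 and Rbl1 at 0.85 ± 0.17 and Tgfb1 at 0.78 ± 0.14. The p53 targets fell as a list (median -0.33, adjusted p = 0.0363; adjusted p = 0.497 with an estimated correlation), and 0 of 25 passed adjusted over the list alone; Ddit4 had -1.16 ± 0.19 and the pro-apoptotic gene Bbc3 -1.01 ± 0.19. Without Hi replicate 2 neither list was called (adjusted p = 0.167 and 0.0687), nor without Lo replicate 1 (adjusted p = 0.22 and 0.434, medians -0.28 and -0.20). Over 14 alternatives the adjusted p ran from 0.0117 to 0.22 for the inhibitor and quiescence genes and from 0.0127 to 0.434 for the p53 targets. Neither list was called after the dim filter (adjusted p = 0.0933 and 0.12) or cyclic loess (adjusted p = 0.0624 and 0.071), nor were the inhibitor and quiescence genes with a replicate block (adjusted p = 0.0716).

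Immediate early and dissociation stress genes fell in Hi (median -0.50, adjusted p = 3.85e-05; adjusted p = 0.252 with an estimated correlation). Of 29 measured members, 10 were lower and 0 higher adjusted over the list alone. Egr1 and the AP-1 subunit gene Jun led, Jun at -1.55 ± 0.14 (SE), while Fos stood at -0.49 ± 0.15. MHC class II genes fell (median -0.98, adjusted p = 8.41e-05; adjusted p = 0.476 with an estimated correlation). Of 8 measured members, 5 were lower and 0 higher adjusted over the list alone. H2-Eb1 had a difference of -1.95 ± 0.16 and Cd74, the invariant chain gene, of -1.54 ± 0.19. Interferon response genes fell (median -0.54, adjusted p = 2.27e-04; adjusted p = 0.571 with an estimated correlation), with 2 of 29 lower adjusted over the list alone, Ddx58 at -0.91 ± 0.13 and Mx2 at -1.88 ± 0.28. Without Lo replicate 2 the interferon list was not called (adjusted p = 0.0939), and over 14 alternatives its adjusted p ran from 2.1e-06 to 0.254.

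Genes of the erythroid lineage rose in Hi (median 1.17, or 0.87 without Hi replicate 2, adjusted p = 2.91e-06; adjusted p = 0.399 with an estimated correlation), and 15 of 26 were higher and 2 lower adjusted over the list alone. Rhag differed by 3.10 ± 0.20 (SE), the membrane skeleton gene Ank1 by 2.66 ± 0.20, the carbonic anhydrase gene Car1 by 2.85 ± 0.35 and the erythropoietin receptor gene Epor by 1.92 ± 0.17. With the mean of all probe sets of a gene Ank1 differed by 1.10. The lineage transcription factor genes Gata1 and Klf1 stood at 1.43 ± 0.29 and 1.76 ± 0.31. The 2 lower members were the transcription factor gene Nfe2 at -0.67 ± 0.15 and the Gata1 cofactor gene Zfpm1 at -0.65 ± 0.18. The probe set shared by the adult beta globin genes was bright in both groups and stood at -0.16 ± 0.40, and 3 shared by the alpha globin genes stood at 0.44 ± 0.29, 0.64 ± 0.44 and 0.66 ± 0.39. Slc4a1 stood at -0.16 ± 0.38, while Alas2 was at or under the dim limit on all 4 arrays.

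Granulocyte and monocyte priming genes rose (median 0.56, adjusted p = 1.45e-05; adjusted p = 0.304 with an estimated correlation). Of 28 measured members, 9 were higher and 0 lower adjusted over the list alone. The granule protein genes Elane, Ctsg and Mpo differed by 2.23 ± 0.21 (SE), 2.29 ± 0.28 and 0.73 ± 0.13, and Ms4a3 by 2.46 ± 0.20, while the transcription factor gene Cebpa stood at 0.26 ± 0.16. Megakaryocyte genes were not called (24 measured, median 0.01, or -0.12 without Lo replicate 2, against a mean of -0.10, adjusted p = 0.894, 0 past 0.05 adjusted over the list alone), with Gp1bb at 0.80 ± 0.15 and the thrombin receptor gene F2r at -0.53 ± 0.13. Multipotent and lymphoid priming genes were not called (30 measured, median -0.15, or -0.03 without Lo replicate 1, adjusted p = 0.317), with 1 member higher and 3 lower adjusted over the list alone. Igll1 had 2.25 ± 0.14 and the chemokine receptor gene Ccr9 -2.70 ± 0.33, while Dntt, the terminal transferase of early lymphoid cells, stood at 0.03 ± 0.15. With the mean of all probe sets of a gene Ccr9 had -1.64.

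**Figure D2:**
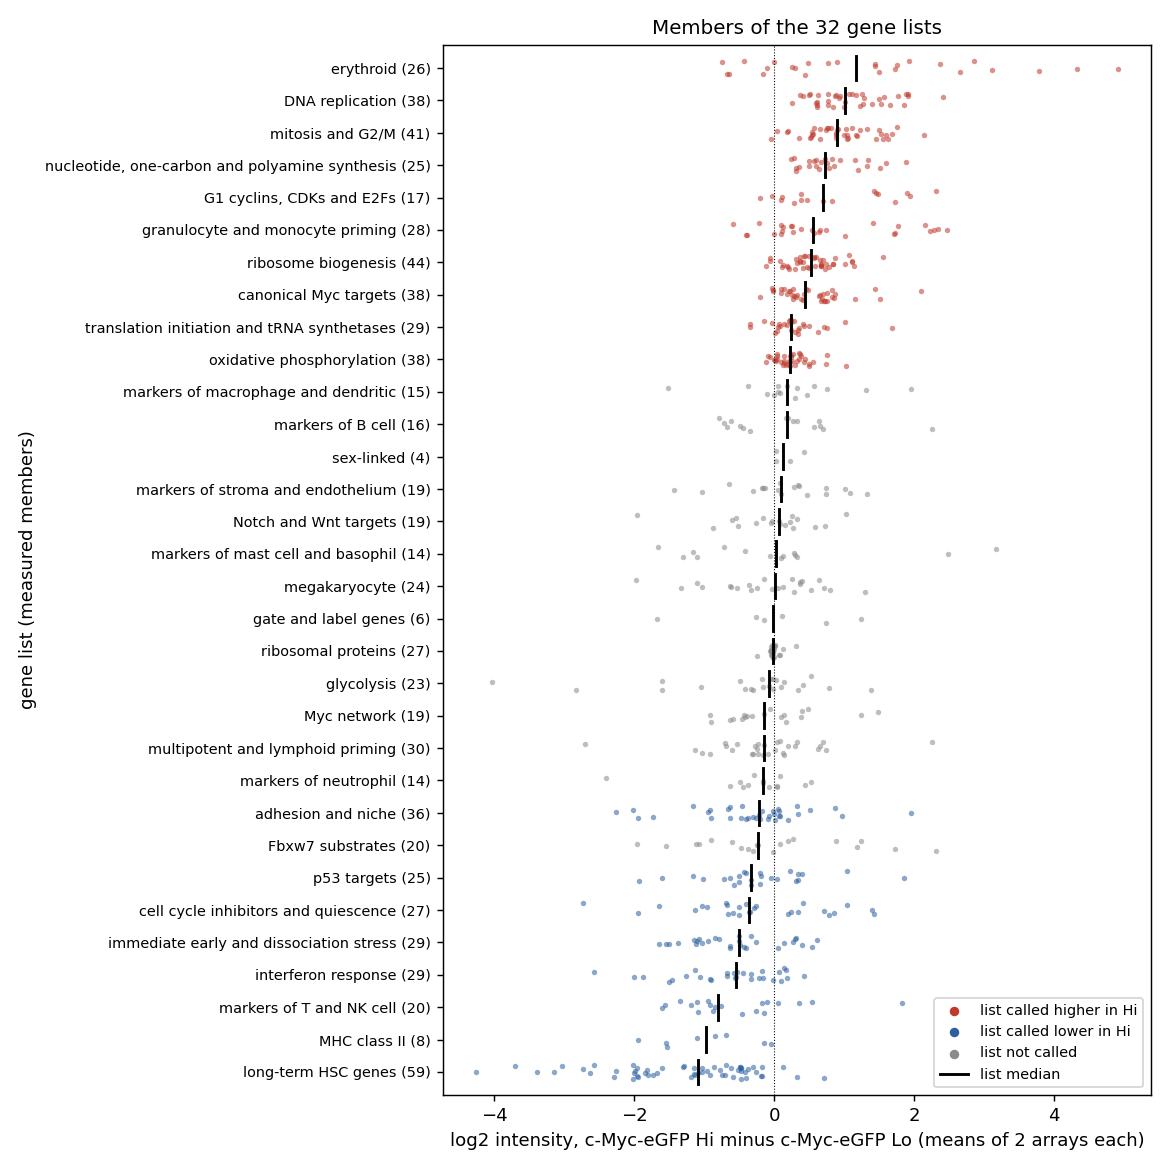
Log2 intensity in c-Myc-eGFP Hi minus Lo (horizontal axis, difference of the means of 2 arrays each) for each measured member of the 32 gene lists (vertical axis, with the number of members); points are genes, black bars list medians, and colours mark lists called higher (red), called lower (blue) or not called (grey) by camera with a preset correlation. Medians run from -1.09 for long-term haematopoietic stem cell genes to 1.17 for erythroid genes.

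Markers of other cell types, fixed as checks of what the gate let through, moved in part. Markers of T and NK cells fell (median -0.81, adjusted p = 0.0107; adjusted p = 0.299 with an estimated correlation), with 1 of 20 lower, Cd8a at -1.19 ± 0.19 (SE), and 1 higher, Cd28 at 1.83 ± 0.29, adjusted over the list alone. With the mean of all probe sets of a gene these were -0.59 and 1.07. This list was not called after a filter on dim probe sets (adjusted p = 0.173), its median was -0.51 without Lo replicate 2, and over 14 alternatives its adjusted p ran from 0.00231 to 0.173. Neutrophil markers were not called (14 measured, median -0.16, adjusted p = 0.347), with Mmp9 at -2.41 ± 0.28 as the 1 member lower adjusted over the list alone and Cxcr2 at 0.44 ± 0.15; the list was called lower without Lo replicate 2 (adjusted p = 0.0135, against 0.703 as the highest of 14 alternatives) and its median was 0.20 without Lo replicate 1 and 0.11 without Hi replicate 2. Markers of macrophages and dendritic cells were not called (15 measured, median 0.18, adjusted p = 0.215, 2 higher and 1 lower adjusted over the list alone), with Itgax at 0.76 ± 0.14, and were called higher without Hi replicate 2 (adjusted p = 0.0305, against 0.679 as the highest of 14 alternatives, with medians from 0.07 to 0.28). Markers of B cells (16 measured, median 0.18, or -0.12 without Hi replicate 1 and -0.05 without Lo replicate 2, adjusted p = 0.845, 1 higher adjusted over the list alone, Igll1; Spib at -0.62 ± 0.16) and of stroma and endothelium (19 measured, median 0.10, from 0.05 to 0.35 over 14 alternatives, adjusted p = 0.625, 1 higher and 1 lower adjusted over the list alone, Plvap at 1.33 ± 0.17 and Emcn at -1.03 ± 0.16) were not called.

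Markers of mast cells and basophils were not called (14 measured, median 0.02, adjusted p = 0.799, with a test direction opposite to the median) and went both ways, with 2 higher and 3 lower adjusted over the list alone. Their median was negative whichever array was left out, from -0.19 to -0.13. The 2 higher were the histidine decarboxylase gene Hdc at 3.17 ± 0.24 (SE) and the basophil protease gene Mcpt8 at 2.49 ± 0.34. The genes of the gate, of its usual subdivision and of the sorted label, that is Kit, Cd34, Flt3, Slamf1, Cd48 and Myc, were not called (6 measured, median -0.02, adjusted p = 0.854, again with a test direction opposite to the median), and 0 passed adjusted over the list alone. Kit stood at -0.27 ± 0.20, Cd34 at 0.11 ± 0.13 and Flt3 at -0.15 ± 0.18, while Cd48 had 0.74 ± 0.19 and Slamf1 -1.68 ± 0.52, or -0.99 without Hi replicate 2 and -1.09 with the mean of all probe sets. The median of this list was 0.07 after the arrays were shifted to 1 median and from 0.02 to 0.05 without Hi replicate 1, Lo replicate 1 or Lo replicate 2. Sex-linked genes were not called (4 measured, median 0.13, or -0.04 without Lo replicate 2, adjusted p = 0.649, 0 past 0.05 adjusted over the list alone). Xist and the Y-linked Kdm5d were both above the dim limit on every array, with means of 11.74 and 8.16 in Hi and 11.31 and 7.93 in Lo, and the difference of Kdm5d was -0.42 with the mean of all its probe sets.

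The Fbxw7 substrates were not called as a list (20 measured, median -0.24, from -0.33 to -0.13 over 14 alternatives, adjusted p = 0.344) and went both ways, with 4 higher and 7 lower adjusted over the list alone. The higher 4 were the cell cycle genes Ccne1, Ccne2, Aurka and Top2a, with Aurka at 1.19 ± 0.17 (SE); the lower 7 were Jun, Junb, Klf2, Mycn, Notch1, Gata2 and Gata3, with Gata3 at -1.96 ± 0.23. Of these 20 genes 13 stand on another list too. The arrays measure transcripts, while the ligase acts on proteins, so this list does not measure ligase activity. Notch and Wnt targets were not called (19 measured, median 0.07 against a mean of -0.07, adjusted p = 0.880). The median was -0.01 without Hi replicate 2 and -0.12 without Lo replicate 2. Adjusted over the list alone 1 was lower, Gata3, and Nrarp stood at 0.73 ± 0.14. Glycolysis genes were not called (23 measured, median -0.08, camera adjusted p = 0.241), and their median was 0.02 after the arrays were shifted to 1 median. Adjusted over the list alone 5 were lower and 0 higher, among them Aldoc, 3.03-fold lower in Hi, and the pyruvate dehydrogenase kinase gene Pdk4 at -4.04 ± 0.53. Pdk4 was 16.4-fold lower, or 10.8-fold without Hi replicate 2, where it was under the dim limit, and 24.9-fold without Hi replicate 1.

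Of the 18 called lists, 9 kept their call in each of 14 alternatives other than the estimated correlation. These were the lists of DNA replication, mitosis, G1 cyclins, nucleotide synthesis, ribosome biogenesis, canonical Myc targets, long-term stem cell genes, immediate early genes and adhesion.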

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

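The tests in this part were chosen after the results were seen, except that of the shared globin probe sets, whose prediction was written before its values were seen; its values without single arrays were added afterwards. The 3 control probe sets for the transferrin receptor transcript, which stand outside the tested probe sets, were looked at again because both Hi arrays lay over 1 log2 unit above both Lo arrays in each. The differences of Hi minus Lo were 2.01 for the 3′ end, 1.91 for the middle and 1.81 for the 5′ end of the transcript, close to the 2.10 of the tested probe set of Tfrc. The 5′ probe set was under the dim limit on both Lo arrays, so its difference is one against background. The 18 spiked hybridization controls differed by at most 0.0729 between the groups.

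The erythroid genes higher in Hi are a pattern with a technical and a biological reading. Red cells or reticulocytes carried into the Hi arrays, which the lineage gate is meant to remove, would bring globin transcripts, and the 4 probe sets shared by the adult globin genes had a median difference of 0.538 (SD 0.383) against 1.17 for the erythroid list, none of whose 26 members stands on another list. Without Lo replicate 2 it was 0.972 (SD 0.403) against 1.25 and without Lo replicate 1 0.0787, so such cells stay open, and the median of -0.00113 for Hba-a1, Alas2 and Slc4a1 decides nothing because Hba-a1 and Alas2 were at or under the dim limit. Erythroid progenitors from outside the gate, which lack Sca1, could dilute Flt3 and Cd34, and the lower of the 2 differences was -0.151 (95% limits -0.651 and 0.350 for Flt3), too wide to settle a modest share. That Hi cells inside the gate carry more erythroid transcript, the difference the sort names, stays open too and was not tested.

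The immediate early genes lower in Hi are the second such pattern, since these genes also respond to cell handling. Handling stress that raised immediate early and heat shock genes together in Lo would leave the heat shock members lower in Hi too. The median of Hspa1a, Hspa1b, Dnajb1 and Hsph1 was 0.414 (SD 0.25) with 0 of 4 below 0, against -0.637 for the other 25 members, of which 21 were below 0. Without Lo replicate 1 the heat shock median was 0.0508 (SD 0.27) with 1 of 4 below 0, so the test rests on that array and does not exclude handling stress. Handling that raised the immediate early genes alone may also account for the pattern, as may a difference between the sorted cells, and neither was tested.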

How the results depend on the processing

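The fit over 1 probe set per gene and the dim filter with an intensity trend were chosen after the data were seen. Of the alternatives chosen beforehand that tested probe sets, the dim filter called 1 higher (Paqr9) and 0 lower. The ordinary test called 0 higher and 1 lower (a dim probe set without a gene name, 2.79 in Hi and 2.97 in Lo). The others that kept every array called 0 and 0, with smallest adjusted p from 0.0598 to 0.193. The mean of all probe sets of a gene, also chosen beforehand but tested on genes, called 252 higher and 276 lower of 18161. The added fit over 1 probe set per gene called 190 higher and 215 lower, and the dim filter with a trend 644 higher and 557 lower. Adjusting the fit to all probe sets over the same 18161 called 0 and 0, and the dim filter alone 1 and 0 of the same 23205. Fewer tests alone therefore did not give these calls. Within each pair the differences and residual variances are the same, and only the prior, that is its variance and its degrees of freedom, is estimated otherwise. Why the prior mattered so much was not tested. The replicate block called 0 higher and 0 lower, 10 lists higher and 7 lower, all but quiescence (adjusted p = 0.0716). Leaving out each array gave 0 and 0 probe sets, 10 to 11 lists higher and 6 to 8 lower; the lone array of a group is there assumed to vary like the other group. Of 10 lists higher and 8 lower, 0 and 0 were called with an estimated correlation, 6 and 3 by fry, and 10 and 5 after the dim filter. With an estimated correlation the test had 2 degrees of freedom, which by itself makes small p-values hard to reach. How much of that loss came from this was not tested, nor was the cause for fry and the dim filter. By fry the erythroid (adjusted p = 0.0533), granulocyte-monocyte (0.0533), oxidative phosphorylation (0.0856), translation (0.103), MHC class II (0.0688), interferon (0.254), quiescence (0.0549), T and NK (0.0641) and p53 (0.214) lists were not called. The medians of 10 lists, none of them called, changed sign in at least 1 alternative. Over 13 alternatives 78 of 81 named genes kept their sign, all but Fbxw7, Xist and Kdm5d. For genes whose Hi and Lo arrays do not overlap, leaving out 1 array cannot change the sign, and most named genes were of this kind. The replicate block, the trend and the array weights leave the difference itself unchanged. With the mean of all probe sets of a gene 19 named genes moved by over 1.5 times and 48 passed 0.05, in a fit that called 252 genes higher and 276 lower of 18161. Below about 4.8 on the log2 scale, signal was not separated from the unspiked controls.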

Other observations

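The tests in this part were chosen after the results were seen, except that of the second granulocyte list. Single genes with large differences on the Hi side were chosen after their values were seen, and no list of them was tested. On the erythroid list, Ermap, which carries the Scianna blood group, was 30.2-fold higher in Hi, or 16.9-fold without Lo replicate 1 and 53.8-fold without Lo replicate 2, and the Rh gene Rhd 13.7-fold. The metallothionein gene Mt2, also on the list, was 20.0-fold higher, or 9.58-fold without Lo replicate 1 and 41.7-fold without Lo replicate 2. Outside that list, the red cell pyruvate kinase gene Pklr was 16.8-fold higher and the Kell gene Kel at least 6.35-fold. The limma adjusted p of these 5 genes ran from 0.0839 for Pklr to 0.122 for Mt2. Paqr9 stood at 9.19 and 9.36 in Hi and under the dim limit on both Lo arrays on the probe set called after the dim filter, and at 9.10 and 9.37 in Hi and 4.66 and 6.82 in Lo on its brighter probe set.

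Single genes with large differences on the Lo side were chosen after their values were seen, and no list of them was tested. The transcription factor gene Bcl11b was 14.3-fold lower in Hi, the T cell receptor gamma segment Trgv1 15.8-fold, Cd7 8.17-fold and the thymocyte gene Themis at least 6.22-fold, with limma adjusted p from 0.0839 to 0.0947. Of the CD3 chain genes, Cd3e had a difference of -0.10, Cd3g of -0.15, Cd3d of -0.77 and the zeta chain gene Cd247 of -1.35. Further genes lower in Hi were the matricellular gene Ccn3 at 26.1-fold, or 16.3-fold without Lo replicate 1 and 41.6-fold without Lo replicate 2, and the growth factor gene Pdgfc at 17.2-fold, with limma adjusted p of 0.0906 and 0.0858. Both were under the dim limit in Hi replicate 1, so these folds are in part against background.

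Some granulocyte transcripts followed the replicate number. Camp had 12.21 and 12.44 in replicates 1 of Hi and Lo and 11.52 and 11.20 in replicates 2, and S100a8 13.03 and 13.11 against 12.52 and 12.60; 9 of the 14 neutrophil markers, none of them on another list, were higher in replicate 1 in both groups, against 23.2% of all genes. Others followed the group, such as Mmp9 at 5.20 and 4.60 in Hi and 7.14 and 7.47 in Lo, and Trem3 at 9.77 and 9.59 in Hi and 7.73 and 6.85 in Lo. Granulocyte RNA carried over to a different degree in the replicate preparations, despite the lineage gate, may account for the markers that followed the replicate number. A second list of 16 granulocyte genes, written before its values were seen, had medians of replicate 1 minus replicate 2 of 0.179 in Hi and 0.0645 in Lo. Of the 16, 7 (43.8%) were higher in replicate 1 in both groups, against 23.2% of all genes. That was short of the share set beforehand, which the neutrophil markers themselves (64.3%) did not reach either. Both medians were above 0, so this test does not decide. Lyz2 on this second list also stands on the granulocyte and monocyte list. The replicate differences of the groups correlated at 0.0719 over all probe sets and at 0.1002 over the brighter ones, which argues against a preparation effect that moved most of the transcriptome alike, and not against a smaller one.

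Between Hi and Lo 8090 probe sets had an unadjusted limma p under 0.05, against at most 1009 in the other splits of the arrays into pairs. Each other split puts 1 Hi and 1 Lo array in both groups, so any difference between Hi and Lo widens the spread within its groups. The counts of the other splits lay under the 2252 expected with no difference and are no measure of chance. Of the 3 splits only 1, the real one, gave as many, and 3 splits are too few for a share under 0.05.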
